A study of Mus musculus with 8 samples.

How the data were processed

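RNA-seq measured transcripts in Treg cells sorted by flow cytometry from the lamina propria of the large intestine of C57BL/6 mice. Per the labels' protocols, RNA was extracted with Trizol and a column kit, ribosomal RNA was removed, and barcoded libraries were pooled over 2 lanes of a HiSeq 2500 and read as 50 bp single-end reads. Of the 8 samples of the series, 4 were RNA-seq and are used here, and the 4 ATAC-seq samples were not analysed here. The values used were the gene counts in the authors' deposited table, whole numbers per gene and library without normalization, with the position of each gene. The same deposited table gave an adjusted p-value per gene, whose comparison is not stated there, and it was read as that of KO against WT. Per the submitters' processing notes, TopHat2, DESeq and the genome build mm9 were used, without versions. The counting tool, the annotation and the use of strand are not given in the sources used here, so reads of overlapping, antisense or near-identical genes cannot be assigned with certainty, and reads shared between histone copies could shift single values. Ribosomal depletion retains transcripts without a poly(A) tail, so histone messages were counted.

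The table held 19191 gene rows, of which 110 had no count in any library and 41 repeated a symbol. The total gene count per library ran from 26862922 to 62402450. A floor of 3 counts was used as the level that a count of 0 allows, and exact 95% Poisson intervals were used for ratios of low counts. Floors and intervals cover counting error only, since reads carried no molecular identifiers. Samples were grouped by the genotype in the labels, with 2 libraries per group, and each column was matched to its sample by title.

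The main test was edgeR 4.0.16 in R 4.3.3, a quasi-likelihood F-test with genotype as the only term, the filterByExpr filter by group (14274 genes kept, 4917 not tested), TMM scaling and a Benjamini-Hochberg adjusted p under 0.05. In this version the function applies the older quasi-likelihood method by default, so the alternative of that name equals the main test. The common dispersion was 0.0328, and the prior degrees of freedom were 3.49 beside 2 residual degrees of freedom. The alternative fit with the replicate number as a block had 1 residual degree of freedom. DESeq2 1.42.0 and limma 3.58.1 (voom) were run as alternatives, and DESeq2 gave an adjusted p for 17996 genes. CPM of single genes are counts scaled to 1000000 of the total over tested genes times the TMM factor of the library. Log2 ratios within a replicate were differences of log2 CPM with a prior count of 2, which draws low genes toward 0. Floors, ratios of low or summed counts, the summed CPM of untested genes and the directions read for the authors' adjusted p-values used the total over all genes with no TMM factor.

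Gene lists were fixed before the data were examined, 18 for functions (Ahr targets, core Treg, Treg effector, Th17, GATA3 and ST2, Th1, follicular helper, gut homing, lymphoid recirculation, proliferation, immediate early, interferon-stimulated, cholesterol synthesis, hypoxia and glycolysis, Nrf2, oxidative phosphorylation, ribosomal protein and replication histone genes) and 13 for other cell types that the sort could hold (epithelial, B, plasma, macrophage, dendritic, neutrophil, mast or basophil, cytotoxic, innate lymphoid, stromal, endothelial, erythroid, enteric glia and neuron). Of 587 members 572 were found in the table. Lists with at least 3 tested genes were tested with camera on log2 CPM (prior count 2, preset correlation 0.01), two-sided, with Benjamini-Hochberg adjustment over the 29 lists. Genes were named by a rule fixed at the same time. It takes Ahr, up to 12 called genes per direction with an average log2 CPM of at least 1, the 5 genes of lowest p per direction where fewer than 5 passed, up to 4 members of lowest p per list, a set of Treg and Ahr genes, Xist and Y-linked genes, and the 5 tested genes on either side of Ahr. Not every gene that the rule takes is reported here. Other genes were named after their values were seen, namely Cxcr3, Epcam and Krt18 and those named only among the other observations.

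Alternatives covered DESeq2 size factors, upper-quartile factors, no filter, a stricter filter (CPM of at least 2 in at least 2 libraries), DESeq2, limma-voom, robust estimation, the replicate number as a block, leaving out each library, an adjusted p under 0.1, a 2-fold minimum, an estimated correlation and fry. The newer quasi-likelihood method, the repeats of the DESeq2 count and the ratios and bounds of low counts and the epithelial contrast without single libraries were chosen after seeing the data. A fit without a library leaves 1 library in a genotype, which is then assumed to vary like the others. Such a fit also compares unequal mixes of the replicates, so a call lost or gained there can reflect the difference between replicates.

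The scripts were tested on simulated data. Counts were drawn for KO against WT with the means and depths of the real libraries. Over 14103 genes the dispersion was set to the common value of 0.0328. There edgeR recovered 49 of 100 genes changed 2-fold and 100 of 100 changed 4-fold with 9 false calls. DESeq2 recovered 50 and 100 with 8 false calls. These recoveries do not give the power in the real data, whose genes need not share that dispersion. In the real data edgeR called 0 genes and missed Ahrr, at a log2 fold change of -4.42 (adjusted p = 0.218). In a simulation of 14089 genes with the Th1 list changed 2-fold, camera called that list and 0 of the others. This simulation does not show that the preset correlation suits the real data. There no list passed with an estimated correlation (camera adjusted p from 0.821 to 0.969).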

Results

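The samples were regulatory T (Treg) cells, the suppressive CD4 T cells defined by the transcription factor Foxp3, sorted by flow cytometry from the lamina propria of the mouse large intestine. Ahr encodes the aryl hydrocarbon receptor, a transcription factor activated by dietary, microbial and environmental ligands. Cre recombinase made from the Foxp3 locus deleted a floxed Ahr allele in these cells. In the libraries called KO the other allele was a null allele, and in those called WT it was intact, so WT Treg cells kept 1 working copy. Total RNA of 2 WT and 2 KO samples was sequenced. The comparison of KO with WT asks which transcripts of gut Treg cells differ when Ahr is lost. By these genotypes, other cells kept 1 working copy in KO mice and 2 in WT mice. Effects within Treg cells therefore cannot be told apart from effects of the surrounding tissue. The total gene count was 26862922 in WT replicate 1, 62402450 in WT replicate 2, 30993483 in KO replicate 1 and 53438828 in KO replicate 2. A count of 0 allowed up to 0.112, 0.0481, 0.0968 and 0.0561 CPM in these libraries, where CPM is a count scaled to a library total of 1000000. In both genotypes replicate 2 was the deeper library, and it held a larger share of counts on Lars2 (1.66% in WT and 0.724% in KO) than replicate 1 (0.0367% and 0.0633%). Log2 ratios of KO over WT within replicate 1 and within replicate 2 are therefore given beside the pooled log2 fold changes, whose errors are standard errors. A positive log2 fold change means higher in KO. The labels do not say that the replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

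Counts over the whole Ahr gene (chromosome 12, 36182646 to 36219710, minus strand, mm9) were nearly as high in KO as in WT. The levels were 581 and 539 CPM in WT and 536 and 518 CPM in KO. The log2 fold change was -0.09 ± 0.09 (95% interval -0.31 to 0.13), with -0.12 in replicate 1 and -0.06 in replicate 2, and the adjusted p was 1.00 (edgeR). A deletion of part of a gene can leave a transcript that is still counted, and counts per gene do not show single exons. The Ahr count therefore checked neither the deletion nor the labels.

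The transcript with the lowest p was Ahrr, the repressor of Ahr that Ahr itself induces (chromosome 13, 74348566 to 74429779, mm9). It stood at 6.92 ± 0.530 CPM in WT and 0.328 ± 0.0893 CPM in KO (SD, n = 2). Its log2 fold change was -4.42 ± 0.31, with -4.07 in replicate 1 and -4.41 in replicate 2. DESeq2 called Ahrr lower (adjusted p = 3.11e-18), as did the authors' deposited table (adjusted p = 1.32e-08). The main edgeR test did not (adjusted p = 0.218), although it did without KO replicate 1 (adjusted p = 0.0145) or without KO replicate 2 (adjusted p = 0.0225), and not without WT replicate 1 (1.00) or WT replicate 2 (0.757). Tiparp, the Ahr-induced ADP-ribosylase, stood at 379 ± 35.2 CPM in WT and 274 ± 4.49 CPM in KO, a log2 fold change of -0.46 ± 0.10 with an adjusted p of 0.0116 in the authors' deposited table and 0.0723 in DESeq2. Of the 8 Ahr target genes tested, 3 were higher and 5 lower, and none passed edgeR over all genes tested, while Ahrr and Tiparp passed when adjusted over the list alone. The log2 fold changes of Nqo1 (-0.72 ± 0.55) and Nfe2l2 (-0.48 ± 0.20) did not pass any of these tests. Cyp1a1 and Cyp1b1, the classical Ahr-induced cytochromes, held 7 and 10 counts over all libraries and could not be tested at this depth. As a set the Ahr targets had a camera adjusted p of 0.0654, which was 0.824 without WT replicate 1, 0.00702 without WT replicate 2, 0.0677 without KO replicate 1 and 0.116 without KO replicate 2. It was 0.915 with an estimated correlation. The directional form of fry, used for fry elsewhere here, gave an adjusted p of 0.534. Its mixed form, which counts changes in either direction, gave 0.0493.

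Across all 14274 genes tested, edgeR's quasi-likelihood test called 0 genes at a Benjamini-Hochberg adjusted p under 0.05, with 234 genes higher and 173 lower at an unadjusted p under 0.05. Together these were a smaller share of the tested genes than the 0.05 that calibrated p-values give by chance, so their number alone is no sign of change. Both KO libraries lay on the same side of both WT libraries in 26.95% of tested genes, against 33.33% for interchangeable libraries. The libraries were not interchangeable, since deviations of same-numbered libraries correlated across genes at 0.641. The main test does not model this, so its p-values need not be calibrated. Neither share therefore decides whether genes changed. DESeq2 called 48 genes, 30 higher and 18 lower, and limma-voom called 0 genes. The authors' deposited table held 66 genes under the same threshold, 31 with a higher and 35 with a lower mean CPM in KO. DESeq2 and the authors' deposited table shared 37 genes. The DESeq2 count fell to 14 genes without WT replicate 1, 22 without WT replicate 2, 29 without KO replicate 1 and 7 without KO replicate 2, and 5 of the 48 genes were called in each of these 4 fits. Those 5 were Ahrr, Gpr15, Cldn25, 4930503L19Rik and Ramp1.

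Beside Ahrr, 3 of these 5 genes were lower in KO by similar amounts. Gpr15, the receptor that guides T cells to the large intestine (chromosome 16, 58717548 to 58718837), stood at 119 ± 0.834 CPM in WT and 57.4 ± 3.24 CPM in KO (SD, n = 2). Its log2 fold change was -1.05 ± 0.10, with -1.10 in replicate 1 and -1.0 in replicate 2 (DESeq2 adjusted p = 9.48e-13, edgeR adjusted p = 0.293). Cldn25, whose annotated start lies on the same chromosome at 58728023, close to Gpr15, had a log2 fold change of -0.92 ± 0.10 (DESeq2 adjusted p = 2.28e-10). The unnamed transcript 4930503L19Rik on chromosome 18 had -1.10 ± 0.10 (DESeq2 adjusted p = 3.25e-13). Wdr69 had -1.17 ± 0.12 (DESeq2 adjusted p = 6.03e-05), a call that was lost in each of the 4 fits without a library, with adjusted p from 0.128 to 0.485. Cldn25 and Wdr69 are the annotated neighbours of Gpr15 and Ccl20. As annotated, Gpr15 and Cldn25 lie 9.19 kb apart and point away from each other, Ccl20 and Wdr69 lie 40.6 kb apart on the same strand, and neither pair overlaps. The 5 genes with the lowest p among those higher in KO were Ramp1, Ccl4, Rasd2, Il21 and Arnt2. Ramp1, a subunit of the receptor for the neuropeptide CGRP (chromosome 1, 93076399 to 93121773), stood at 19.1 ± 0.526 CPM in WT and 42.5 ± 5.71 CPM in KO, a log2 fold change of 1.15 ± 0.13 with 1.31 in replicate 1 and 0.98 in replicate 2 (DESeq2 adjusted p = 2.61e-07, and at most 0.0468 without a library). Rasd2, a Ras-like GTPase, had 1.68 ± 0.21, and Arnt2, a relative of the Ahr partner Arnt, had 0.69 ± 0.10. DESeq2 called both (adjusted p = 9.63e-05 and 2.01e-04), and neither was called in any fit without a library (at least 0.0784 and 0.104). Over 13 alternatives to the main edgeR test, the fit with the replicate number as a block left aside, the adjusted p ran from 3.11e-18 to 1 for Ahrr, from 9.48e-13 to 1 for Gpr15 and from 2.61e-07 to 1 for Ramp1.

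**Figure D1:**
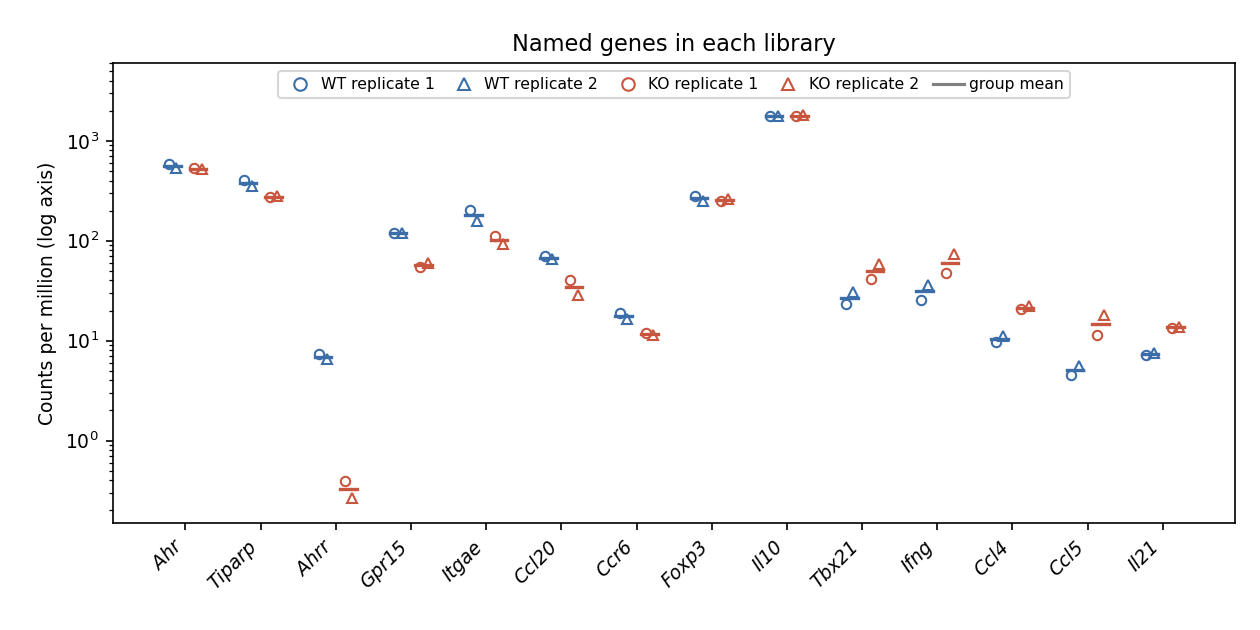
The plot shows CPM on a log axis for 14 named genes in each library, WT in blue and KO in red, with circles for replicate 1, triangles for replicate 2 and a bar for each group mean (n = 2). Ahrr stands at 7.30 and 6.55 in WT and at 0.391 and 0.265 in KO, while Ahr, Foxp3 and Il10 lie at similar levels in both genotypes.

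Genes of tissue homing went both ways. Besides Gpr15, Itgae, the integrin alpha chain CD103 that binds epithelial E-cadherin, was lower at 180 ± 31.1 CPM in WT and 102 ± 13.0 CPM in KO (SD, n = 2), a log2 fold change of -0.82 ± 0.16 with -0.86 in replicate 1 and -0.76 in replicate 2 (DESeq2 adjusted p = 0.00120). The Itgae call was lost without WT replicate 1 and without KO replicate 2, fits that compare unequal mixes of the replicates. With the replicate number as a block, edgeR called Itgae lower (adjusted p = 1.29e-10). Ccr3, an eotaxin receptor, had a log2 fold change of 0.64 ± 0.12 (DESeq2 adjusted p = 0.0221, lost in each fit without a library, lowest adjusted p 0.499), and Itgb1, the integrin beta 1 chain, had 0.46 ± 0.12 (DESeq2 adjusted p = 0.273). Of the 19 homing genes tested, 14 were higher and 5 lower. None passed edgeR over all genes tested, and 4 passed when adjusted over the list alone, Ccr3 and Itgb1 higher and Gpr15 and Itgae lower. The camera adjusted p of the set was 0.171. The lymphoid recirculation genes, such as those for lymph node entry, had 8 of 15 members higher (camera adjusted p = 0.905).

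Ccl20 and its receptor Ccr6, which are linked to Th17 cells, were both lower in KO. Ccl20 stood at 67.7 ± 2.90 CPM in WT and 34.5 ± 8.08 CPM in KO (SD, n = 2), a log2 fold change of -0.98 ± 0.18 with -0.79 in replicate 1 and -1.19 in replicate 2. DESeq2 called Ccl20 lower (adjusted p = 4.45e-04). That call was lost without WT replicate 1 and without KO replicate 2, fits that compare unequal mixes of the replicates. With the replicate number as a block, edgeR called Ccl20 lower (adjusted p = 4.42e-10). Ccr6 had a log2 fold change of -0.59 ± 0.13 and was not called by DESeq2 (adjusted p = 0.665). Both passed edgeR when adjusted over the list alone. Il22 had -0.42 ± 0.18 and Il17a had -0.07 ± 0.37 with 0.27 in replicate 1 and -0.63 in replicate 2. Of the 18 Th17 genes tested, 10 were higher and 8 lower, none passed edgeR over all genes tested, and the camera adjusted p was 0.905.

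Core Treg genes showed no called difference by edgeR with genotype as the only term, and the intervals were narrow for the main ones. Foxp3 stood at 266 ± 19.7 CPM in WT and 255 ± 6.25 CPM in KO (SD, n = 2), a log2 fold change of -0.06 ± 0.09 (95% interval -0.29 to 0.17). The suppressive cytokine gene Il10 stood at 1765 ± 6.76 and 1786 ± 6.82 CPM, a log2 fold change of 0.02 ± 0.09 (95% interval -0.21 to 0.25). Ikzf2, which encodes Helios, had -0.05 (95% interval -0.39 to 0.28), and Klrg1 had 0.05 (95% interval -0.19 to 0.29). The inhibitory receptor gene Ctla4 had 0.24 ± 0.10 (95% interval -0.01 to 0.50), the ectonucleotidase gene Entpd1 had 0.42 ± 0.12, and Pdcd1, which encodes PD-1, had 0.36 ± 0.11. Cd83 had -0.45 ± 0.09, and DESeq2 called it lower (adjusted p = 0.0170, at least 0.538 without a library). Of 21 core Treg genes, 13 were higher and 8 lower (camera adjusted p = 0.429), and of 16 Treg effector genes, 9 were higher and 7 lower (camera adjusted p = 0.609). With genotype as the only term, none of either list passed edgeR over all genes tested or when adjusted over the list alone. With the replicate number as a block, edgeR called Cd83 lower (adjusted p = 1.04e-05) and Entpd1 (2.24e-04), Pdcd1 (3.03e-04) and Ctla4 (0.0389) higher. That fit has 1 residual degree of freedom, so its small p-values rest largely on variance estimates shared across genes. Foxp3, Il10, Ikzf2 and Klrg1 were not called with that block (at least 0.802).

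Genes of the Th1 program rose as a set in KO (camera adjusted p = 0.00343 over 15 genes, 10 higher and 5 lower, median log2 fold change 0.18). This call was lost with an estimated correlation (adjusted p = 0.821) and without KO replicate 1 (adjusted p = 0.0585), and was kept by fry (adjusted p = 0.00727). Tbx21, which encodes the Th1 regulator T-bet, stood at 26.9 ± 5.39 CPM in WT and 49.8 ± 12.1 CPM in KO (SD, n = 2), a log2 fold change of 0.89 ± 0.22 with 0.84 in replicate 1 and 0.93 in replicate 2. Ifng, the gene of interferon gamma, had 0.96 ± 0.27 with 0.86 and 1.02. The chemokine genes Ccl4 and Ccl5 had 1.04 ± 0.13 and 1.53 ± 0.26, and Cxcr3, a chemokine receptor gene of Th1 cells, had 0.48 ± 0.14. These 5 genes passed edgeR when adjusted over the list alone, and none passed over all genes tested. DESeq2 called 4 of them (adjusted p = 0.0337 for Tbx21, 0.0497 for Ifng, 2.01e-04 for Ccl4 and 4.51e-04 for Ccl5). Without WT replicate 1 all 4 calls were lost, likewise without KO replicate 2. Ccl4 was also lost without WT replicate 2 and without KO replicate 1. Those fits compare unequal mixes of the replicates. With the replicate number as a block, edgeR called all 4 higher (adjusted p from 4.42e-10 for Ifng to 4.59e-08 for Ccl4). That fit has 1 residual degree of freedom.

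Among follicular helper genes, Il21 stood at 7.32 ± 0.242 CPM in WT and 13.6 ± 0.195 CPM in KO (SD, n = 2), a log2 fold change of 0.89 ± 0.13 with 0.91 in replicate 1 and 0.87 in replicate 2. DESeq2 called Il21 higher (adjusted p = 0.0268, lost in each fit without a library with 1.00), and it alone passed edgeR when adjusted over the list of 11 genes, of which 9 were lower (camera adjusted p = 0.311, and 0.0488 without WT replicate 2 or 0.0375 without KO replicate 1). The type 2 genes Gata3, Il1rl1 (the receptor ST2), Ccr8 and Pparg had log2 fold changes of 0.10 ± 0.27, 0.35 ± 0.23, 0.32 ± 0.09 and 0.64 ± 0.20. None of the 14 genes of that list passed edgeR over all genes tested or when adjusted over the list alone, and 7 were higher and 7 lower (camera adjusted p = 0.429).

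Replication-dependent histone genes were higher in 29 of 30 cases, with a median log2 fold change of 0.28 (0.29 in replicate 1 and 0.24 in replicate 2, camera adjusted p = 1.15e-09, and at most 0.00238 without a library). The call was lost with an estimated correlation (adjusted p = 0.821) and with fry (adjusted p = 0.534). Examples were Hist1h2ak (0.45 ± 0.10) and Hist1h2ad (0.50 ± 0.12). Reads of these near-identical copies can be shared, so single histone values are uncertain. Proliferation genes were higher in 33 of 35 cases, median 0.17 (0.16 in replicate 1 and 0.17 in replicate 2, camera adjusted p = 0.0116). The call was lost with an estimated correlation (adjusted p = 0.915) and with fry (adjusted p = 0.993). The direction of this set turned without WT replicate 1 and without KO replicate 2. Those fits compare unequal mixes of the replicates, and Mki67 was higher in replicate 2 (341 CPM in WT and 402 in KO) than in replicate 1 (234 and 271). Pcna had 0.20 ± 0.10, Tyms 0.27 ± 0.15, Mcm6 0.15 ± 0.09 and Mki67 0.23 ± 0.25. Genes of hypoxia and glycolysis were higher in 22 of 24 cases, median 0.12 (camera adjusted p = 0.0116). That call was lost with an estimated correlation (adjusted p = 0.915), with fry (0.691), without WT replicate 2 (0.130) and without KO replicate 2 (0.493). The glucose transporter gene Slc2a1 had 0.27 ± 0.14, Ldha 0.16 ± 0.08 and Ankrd37 0.28 ± 0.13. No member of the 3 sets passed edgeR over all genes tested or when adjusted over the list alone.

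The other function sets did not pass. Oxidative phosphorylation genes had 26 of 34 members higher (camera adjusted p = 0.0512), and interferon-stimulated genes had 24 of 33 lower (0.0552). Immediate early and stress genes had 19 of 25 higher (0.176), cholesterol synthesis genes 19 of 23 (0.297), Nrf2 targets 14 of 17 (0.429) and ribosomal protein genes 40 of 66 (0.899). None of their members passed edgeR over all genes tested or when adjusted over the list alone. Without KO replicate 1 the interferon-stimulated set passed as lower (0.0131) and the cholesterol synthesis set as higher (0.0113), and without WT replicate 1 the interferon-stimulated set passed again (0.0228) and the immediate early set as higher (0.0150).

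**Figure D2:**
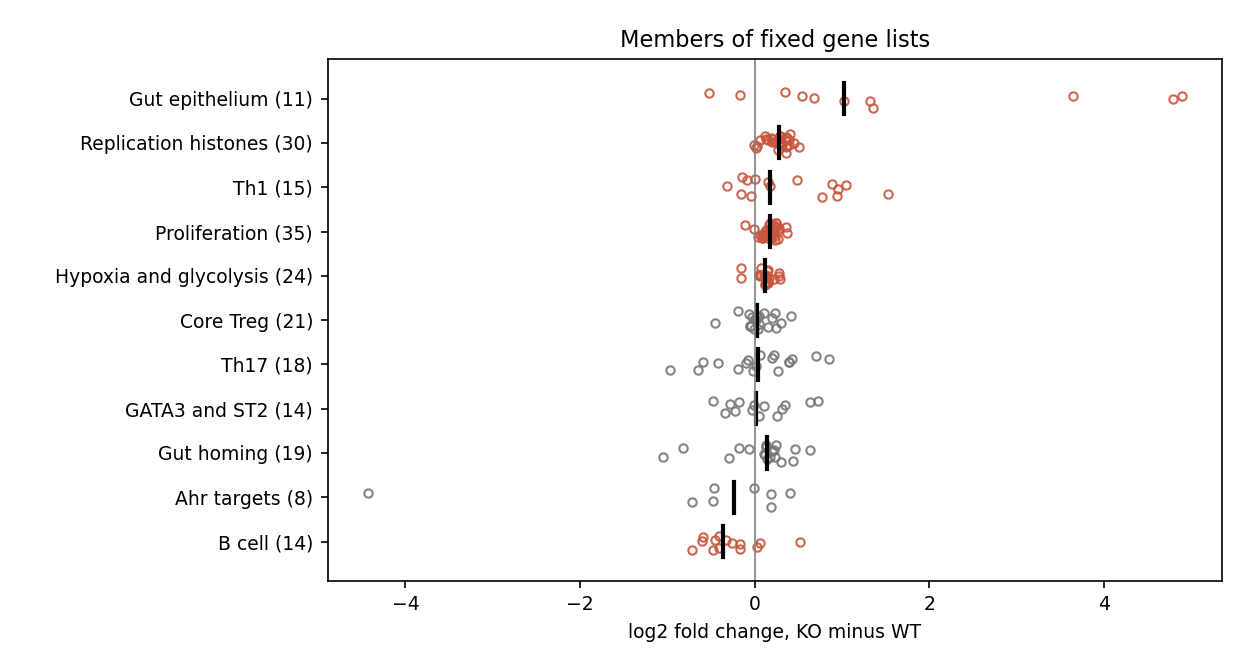
Each open circle is the log2 fold change, KO minus WT, of 1 tested member of a fixed gene list, with the number of tested members in brackets and a black bar at the median. Lists in red had a camera adjusted p under 0.05, and the median was 1.03 for gut epithelium, 0.28 for replication histones and -0.36 for B cells.

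Markers of other cell types moved with genotype in 2 of 11 lists tested. Gut epithelial genes rose in KO, with 9 of 11 members higher and a median log2 fold change of 1.03 (0.70 in replicate 1 and 1.21 in replicate 2). The camera adjusted p was 2.38e-04, at most 0.00226 without a library, but 0.894 with an estimated correlation and 0.588 with fry. The keratin gene Krt8 had 8 counts in WT and 235 in KO, a ratio of 31.1 (exact 95% interval 15.5 to 72.8). Krt19 had 4 and 146 counts, a ratio of 38.6 (14.8 to 144), and the colonocyte carbonic anhydrase gene Car1 had 20 and 229, a ratio of 12.1 (7.66 to 20.2). KO replicate 2 held 204, 129 and 201 of the KO counts of Krt8, Krt19 and Car1, and without it the ratios were 11.2 (5.02 to 28.1), 12.2 (3.99 to 50.0) and 4.03 (2.19 to 7.55). These intervals cover counting error only. Each of these 3 genes was higher in both KO libraries, and KO replicate 2 held the highest level, at 3.86 CPM for Krt8, 2.44 CPM for Krt19 and 3.80 CPM for Car1. DESeq2 called Krt8 (adjusted p = 8.00e-04, lost without WT replicate 2, KO replicate 1 or KO replicate 2, with adjusted p from 0.0972 to 1.00). Epcam (-0.17 ± 0.12) and Krt18 (-0.53 ± 0.30) were not higher. B cell genes fell, with 11 of 14 members lower, a median of -0.36 (-0.14 in replicate 1 and -0.45 in replicate 2) and a camera adjusted p of 0.00111. That call was lost without KO replicate 2 (adjusted p = 0.247), with an estimated correlation (adjusted p = 0.821) and with fry (adjusted p = 0.588). H2-Ob had -0.45 ± 0.10 and Cd79b had -0.33 ± 0.17. No member of either list passed edgeR over all genes tested or when adjusted over the list alone.

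The remaining cell type lists did not pass. Innate lymphoid genes had 6 of 9 members lower (camera adjusted p = 0.0512), and Kit, a stem cell factor receptor gene, stood at 11.5 ± 1.11 CPM in WT and 5.54 ± 0.877 CPM in KO (SD, n = 2, DESeq2 adjusted p = 0.0294, at least 0.263 without a library). Kit also passed edgeR when adjusted over the list alone. Monocyte and macrophage genes had 13 of 16 members lower (0.176), with Ccr2 at 0.13 ± 0.11, and dendritic cell genes 7 of 10 lower (0.819). Cytotoxic genes of CD8 T and NK cells went both ways (0.811), with Gzma at -1.58 ± 0.39 and Nkg7 at 1.01 ± 0.33. The camera adjusted p was 0.285 for plasma cell genes, 0.868 for endothelial genes, 0.905 for erythroid genes and 0.899 for enteric glia and neuron genes, where Prph (higher) and Ret (lower) passed edgeR when adjusted over the list alone. Stromal genes had a median of 0.13 and a mean of 0.05, while the set test pointed lower (0.868). Without single libraries some of these sets passed. The innate lymphoid set was lower without WT replicate 2 (0.0219) or KO replicate 1 (0.0126), and the macrophage set likewise (0.00191 and 7.21e-04). The endothelial set was higher without WT replicate 2 (0.0283) or KO replicate 1 (0.0312). The stromal set was lower without WT replicate 1 (0.0254) or KO replicate 2 (1.65e-04) and higher without KO replicate 1 (0.0312), and the erythroid set was lower without WT replicate 1 (0.00717) and higher without WT replicate 2 (0.0159). Neutrophil and mast cell or basophil lists had fewer than 3 tested genes each and were not tested.

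Y-linked transcripts were present in all 4 libraries, while Xist, named by the same rule, was not among the tested genes. The Y-linked genes given here all had a positive log2 fold change, and a difference in the share of male cells between genotypes was not tested. Ddx3y stood at 155 and 135 CPM in WT and 208 and 261 CPM in KO, a log2 fold change of 0.69 ± 0.14 with 0.42 in replicate 1 and 0.96 in replicate 2 (DESeq2 adjusted p = 0.00717). That call was lost without WT replicate 2, without KO replicate 2 and with the replicate number as a block in DESeq2 (adjusted p = 0.836). Uty had 0.47 ± 0.18, Eif2s3y had 0.99 ± 0.39 and Kdm5d had 0.60 ± 0.39, with -0.11 in replicate 1 and 1.03 in replicate 2. Around Ahr on chromosome 12, the gene Prps1l1 (35669433 to 35671108) had 57 counts in WT and 0 in KO, at least 17.97-fold lower in KO when 3 counts over the group are taken as the floor (DESeq2 adjusted p = 0.0447). That call was kept in 0 of the 4 fits without a library, and DESeq2 gave no adjusted p without WT replicate 1 or WT replicate 2. It was also lost with the replicate number as a block in DESeq2. The other 9 tested genes nearest to Ahr, Snx13 (-0.25 ± 0.12) among them, had log2 fold changes from -1.21 to 0.10, and 0 of them had an unadjusted p under 0.05 in edgeR.

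**Figure D3:**
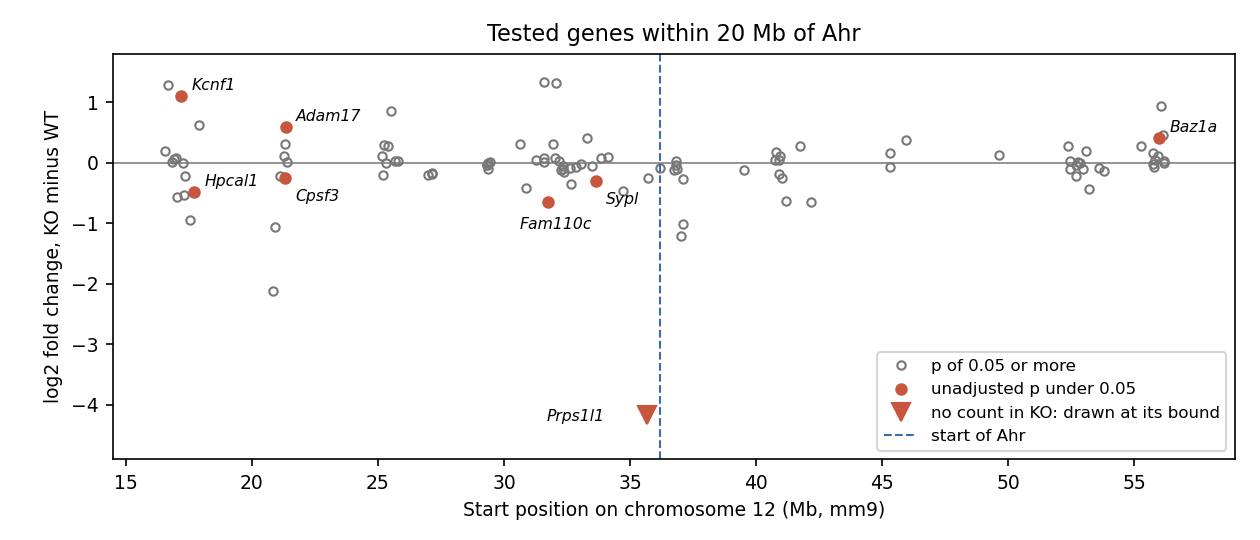
Each circle is a tested gene within 20 Mb of the start of Ahr (dashed line) on chromosome 12, placed by its annotated start in mm9 and its log2 fold change, KO minus WT, with genes of unadjusted edgeR p under 0.05 filled in red. The triangle marks Prps1l1, without counts in KO, at its bound of 17.97-fold lower, and 8 of the 109 genes drawn are marked in red.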

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

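The newer quasi-likelihood method and the DESeq2 repeats were chosen after seeing the data. The edgeR count stayed at 0 genes under DESeq2 size factors, upper-quartile factors, the stricter filter, limma-voom, robust estimation, both quasi-likelihood methods, an adjusted p under 0.1 and a 2-fold minimum, with 407 genes at an unadjusted p under 0.05 in edgeR. It was 52 genes (36 higher, 16 lower) with no filter, where the prior degrees of freedom rose from 3.49 to 19.2, 48 with DESeq2, and 0 to 2 without a library (2 without KO replicate 1, 2 without KO replicate 2). Of the DESeq2 genes 43 were among the 52. With the replicate number as a block, which leaves 1 residual degree of freedom, it was 458 genes (275 higher, 183 lower). Of the 48 DESeq2 genes 47 were among them. DESeq2 with that block called 139 (91 higher, 48 lower), 43 of the 48 among them. Ddx3y, Dmbt1, Ckmt1, Prps1l1 and Sprr2a3 were lost there. The labels share only a number, and deviations of same-numbered libraries correlated across genes at 0.641. Log2 CPM correlated more closely between same-numbered libraries of opposite genotype (0.991 in replicate 1 and 0.988 in replicate 2) than between libraries of the same genotype (0.981 in WT and 0.977 in KO). The main test does not model this. DESeq2 called 48 genes without Lars2 and 4 repeat-rich genes, the same 48, and 7 to 29 without a library. The cause of these differences was not tested. Lists that passed numbered 6 with TMM, 6 with DESeq2 size factors, 11 with the replicate block (which adds macrophage, 1.34e-04, dendritic, 0.010, innate lymphoid, 0.0312, and follicular helper, 0.0350, as lower and oxidative phosphorylation, 0.0304, as higher), 4 to 12 without a library, 1 with fry and 0 with an estimated correlation (adjusted p from 0.821 to 0.969 over the 29 lists).

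Lists that changed direction in at least 1 fit without a library had these ranges of adjusted p over the 4 fits: core Treg 0.0679 to 0.713, Treg effector 0.130 to 0.746, Th17 0.130 to 0.296, GATA3 and ST2 0.0865 to 0.739, follicular helper 0.0375 to 0.925, recirculation 0.261 to 0.713, proliferation 9.12e-08 to 0.348, immediate early 0.0150 to 0.974, cholesterol synthesis 0.0113 to 0.824, ribosomal proteins 0.493 to 0.936, plasma cell 0.0542 to 0.877, macrophage 7.21e-04 to 0.719, dendritic 0.0608 to 0.225, cytotoxic 0.264 to 0.844, stromal 1.65e-04 to 0.136, endothelial 0.0283 to 0.133, erythroid 0.00717 to 0.733, and enteric glia and neuron 0.636 to 0.968. Direction also turned with fry for Th17 (0.993) and for enteric glia and neuron (0.534), and with the replicate block for stromal (0.989). Log2 fold changes that changed sign without a library ran from -0.087 to 0.52 for Mki67, -0.14 to 0.014 for Foxp3, -0.019 to 0.12 for Klrg1, -0.22 to 0.086 for Ikzf2, -0.21 to 0.50 for Gata3, -0.77 to 0.40 for Il17a and -0.17 to 1.08 for Kdm5d. Ahr ran from -0.14 to -0.03. The cause was not tested. No scaling moved the median log2 fold change of all genes by over 0.1. Each scaling used centres most genes near 0, so this could not show a shift shared by most genes. Depth limits transcripts near the floor of 0.0481 to 0.112 CPM, Cyp1a1 and Cyp1b1 among them.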

Other observations

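The tests on cell share and on the Ahr region were chosen only after the result was seen. The tests on epithelial genes too low for edgeR and on neighbouring genes were written down before their values were computed, although some neighbouring pairs had been noticed. Further transcripts typical of gut epithelium, outside the fixed list and chosen after their values were seen, were higher in KO, and DESeq2 called all of those named here but Mep1a. Dmbt1, a secreted mucosal defence protein, stood at 0.261 and 0.0310 CPM in WT and 1.34 and 5.70 CPM in KO (DESeq2 adjusted p = 4.45e-04). Tgm3, a transglutaminase, stood at 0 and 0.0310 CPM in WT and 0.782 and 2.38 CPM in KO (DESeq2 adjusted p = 0.00352). Slc6a4, the serotonin transporter gene, stood at 0.0370 and 0.283 CPM in WT and 2.35 and 3.42 CPM in KO (DESeq2 adjusted p = 1.69e-04). Ckmt1, a mitochondrial creatine kinase gene, had 0 counts in WT and 163 in KO, at least 57.4-fold higher with 3 counts over the group as the floor, or 19.2-fold without KO replicate 2, which held 143 of these counts. Mep1a, a brush border protease gene, had 0 and 34 counts, at least 11.98-fold higher, or 8.64-fold without KO replicate 2, which held 25 of them, and was not called by DESeq2 (adjusted p = 0.522). Without KO replicate 2 the DESeq2 calls of Dmbt1, Tgm3, Slc6a4 and Ckmt1 were lost, likewise without WT replicate 2, and those of Tgm3 and Ckmt1 without WT replicate 1. With the replicate number as a block, DESeq2 lost Dmbt1 (adjusted p = 0.411) and Ckmt1 and kept Tgm3 (2.06e-04) and Slc6a4 (4.15e-06).

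Further genes called by DESeq2 were chosen after their values were seen. Prr5l, a regulator of mTORC2, had a log2 fold change of -1.50 ± 0.17, Frmd5 had -1.07 ± 0.12, Rasgrp4 had -0.86 ± 0.11, Hic1, a transcriptional repressor of intestinal lymphocytes, had -0.81 ± 0.12, and Gbp1, an interferon-induced GTPase, had -1.09 ± 0.18. Asb2, Lpar6 and Rcbtb2 had -0.53 ± 0.09, -0.57 ± 0.10 and -0.59 ± 0.11. On the higher side, the growth factor gene Csf1 had 0.81 ± 0.14, the serine protease inhibitor gene Serpina3f had 1.26 ± 0.21, the chemokine gene Ccl9 had 2.65 ± 0.44, the semaphorin gene Sema7a had 1.12 ± 0.20, Chsy1 had 0.71 ± 0.11 and S100a4 had 0.63 ± 0.15. The DESeq2 adjusted p was 5.44e-05 for Prr5l and for Gbp1, 1.57e-05 for Frmd5, 9.02e-06 for Serpina3f and 2.69e-04 for Csf1, and reads of Serpina3f can be shared with its close copies. Of these, Gbp1 was lost only without WT replicate 2 (0.191) and Serpina3f only without KO replicate 2 (0.0641), while Prr5l and Frmd5 were lost in each fit without a library (at least 0.0858 and 0.0714), and Csf1 without WT replicate 1 (0.177) and KO replicate 2 (0.739). Hic1 was also lost without these libraries (0.461 and 0.866), and Chsy1, Sema7a and S100a4 were kept only without WT replicate 2 (0.0386, 0.00272 and 7.94e-04). Rasgrp4, Asb2, Lpar6, Rcbtb2 and Ccl9 were lost in each fit without a library (at least 0.313, 0.265, 0.396, 0.554 and 0.641).

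Epithelial transcripts were higher in KO although the cells had been sorted by flow cytometry. A lower share of Treg cells in the KO libraries would raise markers of every other cell type. The 11 epithelial genes lay 1.98 log2 units in the mean above 30 B cell and macrophage genes (1.11 to 3.00 without a library). The median of the 30 genes was -0.41 (SD 0.42) and that of the epithelial genes 1.03 (SD 1.92). In each fit without a library these medians differed by at least 0.82. This gap exceeded the SD of the 30 genes but not that of the epithelial genes. B cell and macrophage genes thus lacked a matching rise, which is not evidence of a fall. The comparison does not decide on the share of Treg cells, since both lists were chosen after the result was seen. Not every member need mark another cell type either, as Ccr2 of the macrophage list stood at 1364 CPM in WT. Without KO replicate 2 the B cell call was lost, the macrophage set turned direction (also without WT replicate 1) and the median of the 30 genes was 0.04. The comparison covers B cell and macrophage genes only. Medians of other lists were positive for stromal (0.13), endothelial (0.15), plasma cell (0.27) and enteric glia and neuron genes (0.32). They were negative for dendritic (-0.36), cytotoxic (-0.33), innate lymphoid (-0.27) and erythroid genes (-0.29). Carry-over of epithelial RNA or cells may be the source. The 5 epithelial genes too low to test summed to 4 and 7 counts in WT and 9 and 51 counts in KO. Their CPM ratio was 5.77 (exact 95% interval 3.00 to 12.2), but 2.36 (0.863 to 6.26) without KO replicate 2. The rise lay in Krt20 (2 and 0 counts in WT, 4 and 18 in KO) and Cldn3 (1 and 0, 4 and 25). Car4 (0 and 2, 0 and 2), Tff3 (1 and 2, 0 and 6) and Aqp8 (0 and 3, 1 and 0) were not higher in both KO libraries, so this sum does not decide the source. Krt18, the partner of Krt8, and Epcam were not higher, at 2.14 and 14.6 CPM in WT and 1.48 and 13.0 CPM in KO, and expression by the KO Treg cells, or a difference of the tissue between genotypes, remains open and was not tested.

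Low p-values were more frequent within 20 Mb of Ahr, where only KO carries the null allele, but 5 of the 8 genes lay 14.9 to 19.8 Mb away, 3 lay within 5 Mb, and besides Prps1l1 0 of the 9 tested genes nearest to Ahr had one. In this window 8 of 109 tested genes (7.34%) had an unadjusted edgeR p under 0.05, against 2.82% elsewhere (Fisher's exact test, p = 0.0127), Prps1l1, Adam17 (0.59 ± 0.09), Hpcal1 (-0.49 ± 0.17), Fam110c (-0.65 ± 0.20) and Kcnf1 (1.10 ± 0.42) among them. Chance clustering was argued against only weakly, as 2.97% of 11958 windows of 109 genes elsewhere held as many (median 3, highest 17), and the region was chosen after it had been seen. Reads lost at variants of the null allele's strain cannot be told apart from other explanations, as 62.5% of the 8 genes were lower in KO against 42.1% elsewhere (Fisher's exact test, p = 0.293), and 8 genes are too few. Variants linked to the null allele are a candidate explanation, regulation by Ahr another, and neither was tested.

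Neighbouring genes moved together more often than in shuffled gene orders, with 36 of 14253 neighbouring pairs having an unadjusted edgeR p under 0.05 and 1 direction, against 5.90 on average (permutation p = 1e-05, the smallest that 100000 resamples can give), Gpr15 with Cldn25 and Ccl20 with Wdr69 among them. Overlapping annotation as the whole cause was argued against, since 30 pairs did not overlap (5.32 in shuffled orders, permutation p = 1e-05). Reads shared by paralogs as the whole cause were argued against too, since 17 pairs neither overlapped nor shared the first 3 letters of their symbols (5.01 in shuffled orders, permutation p = 3e-05). The 17 pairs included Eif2s3y with Uty and Uty with Ddx3y on the Y chromosome. They also included S100a6 with Sprr2a1 (1601 kb apart) and 5430421N21Rik with Krt8 (505 kb apart), so not all were close neighbours. Reads that run on past a gene's end cannot be told apart from shared regulation, although 5 divergent pairs were found (1.34 in shuffled orders, permutation p = 0.012). That count had been written down beforehand as evidence against run-on reads, but it was the wrong bound because it kept paralogs, and without them 3 pairs were left (1.30 in shuffled orders, permutation p = 0.14). Shared regulation of neighbours remains a hypothesis found on the same data, and no test here decides it.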
